A study of Rattus norvegicus with 24 samples.

How the data were processed

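RNA from the CA1 field of the hippocampus of male Long-Evans rats was measured on Affymetrix rat expression arrays, with 1 array per biological replicate. Groups followed the labels: young (6 months, 9 arrays), aged with unimpaired spatial learning (24 to 26 months, 6 arrays) and aged with impaired spatial learning (24 to 26 months, 8 arrays). The labels name no aged unimpaired replicate 6, and the column of young replicate 9 lies between those of aged unimpaired replicates 5 and 7. It was kept as young, as labelled. The deposited table held 31099 probe sets in 24 sample columns, of which 1 was blank in every probe set. That column belonged to an aged unimpaired array that the submitters omitted after quality control, so 23 arrays were analysed. The deposited values were log2 signals that the authors made with GCRMA, per the submitters' processing notes, which corrects background, normalizes and summarizes probes into probe sets. The version of GCRMA and its settings were not given in the sources used here. Values were used as deposited, without further scaling.

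Of the probe sets, 20832 carried exactly 1 gene symbol, 436 carried several and 9831 carried none. Each gene was represented by its probe set with the highest mean over the 23 arrays, among those with a log2 signal over 4 in at least 6 arrays, which left 9076 genes. A model of the 3 group means was fitted with limma 3.58.1 in R 4.3.3, with moderated tests and Benjamini-Hochberg adjustment within each of 4 comparisons, and genes with an adjusted p under 0.05 were called. The mean of the aged rats weighted the aged groups by their 8 and 6 arrays. The median standard error of a log2 difference was 0.0582 for aged against young, 0.0662 for impaired against young, 0.0718 for unimpaired against young and 0.0736 for impaired against unimpaired. The pipeline was tested on simulated data with 200 planted changes among 9076 genes in 10 runs. A planted log2 change of 0.25 was recovered in 62.8%, 54.2%, 48.8% and 43.6% of cases in these comparisons, and a change of 0.5 in 93.8%, 91.4%, 87.6% and 89.6%. Changes of 0.25, 0.5, 1 and 2 were planted together, in genes simulated independently. Where few genes truly differ, the adjusted threshold is stricter than in these runs. The shares recovered therefore do not give the power of a comparison without calls, such as impaired against unimpaired. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

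All gene lists, the panel and the rule for naming genes were fixed before the data were examined. For each comparison the rule named the 12 called genes with the largest rise and the 12 with the largest fall, and where fewer than 5 genes were called, the 5 with the smallest p in each direction. Up to 4 members with the smallest p were open to naming in each list described. The panel was Gfap, Cd74, C3, C4a, C4b, C1qa, Mbp, Ttr, Npy, Sst, Gad1, Gad2, Reln, Bdnf, Arc, Egr1 and Calb1. Of 43 lists of pathways, cell types and neighbouring regions, 42 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over their list alone. The age score was compared between the aged groups with a 2-sided exact permutation test over all splits of the aged arrays.

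The changes of the aged groups against young share the young arrays. Their correlation was therefore set beside 100 simulations of unchanged groups, and it and the overlap of calls beside 126 splits of the young arrays into 4 and 5. Alternatives covered the filter, the choice of probe sets, normalization, array weights, moderation, a covariate for RNA quality, a block by replicate number, the threshold, the groups in the fit, the set test, the genes in the age score and leaving out each array in turn. A fit without the 3 arrays of lowest correlation with the others was added after the data were seen. No batch or date of processing was given, so none was modelled.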

Results

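Total RNA from the CA1 field of the hippocampus, a region of pyramidal neurons needed for spatial learning, was measured on genome-wide rat expression arrays in male Long-Evans rats. Of the 23 arrays analysed, 9 came from young rats of 6 months and 14 from aged rats of 24 to 26 months. The aged rats had been tested in the Morris water maze, in which a rat learns the place of a hidden platform. A learning index put 6 of them within the range of the young rats (aged unimpaired) and 8 of them outside it (aged impaired). The groups are those of the labels. The labels name no aged unimpaired replicate 6, and young replicate 9 stands among the aged unimpaired arrays in the deposited table. Each array was a separate biological replicate by its label, and the number of arrays sets the precision of every comparison. The column of 1 more aged unimpaired array, which the submitters had left out after quality control, held no values and was not used. The median signal of an array lay between 4.2 and 4.28 on the log2 scale, and its median correlation with the other arrays across genes lay between 0.990 and 0.994. The difference between 3 prime and 5 prime control probe sets, a sign of RNA quality, did not separate the groups. Its 2-sided exact permutation p was 0.534 for impaired against young, 0.113 for unimpaired against young and 0.213 for impaired against unimpaired arrays. The median correlation with the other arrays was higher in aged unimpaired than in young arrays by 0.00101 (exact p = 0.0248), and lower in aged impaired than in aged unimpaired arrays by a difference of -0.00133 (exact p = 0.0433). After dim probe sets were left out, 9076 genes were tested.

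The first comparison asked what differed between aged and young CA1 whatever the learning of the aged rats. The 2 largest rises were those of immune transcripts. Cd74, the chain that escorts MHC class II molecules, was 7.98-fold higher in aged CA1, at 7.48 ± 1.19 (SD, n = 14) against 4.49 ± 0.41 (SD, n = 9) log2 units. The central complement protein C3 was 7.66-fold higher, at 7.18 ± 0.88 against 4.24 ± 0.83. Mgst1, a membrane-bound glutathione transferase, gave the smallest p of all genes, at 2.74-fold higher. Among the genes that fell, the secreted guidance protein Sema3c was 2.95-fold lower and the basement membrane protein Nid1 1.91-fold lower in aged CA1. Of the inhibitory neuron markers Npy, Sst, Gad1, Gad2 and Reln, none passed the test.

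With limma and Benjamini-Hochberg adjustment, 280 genes rose and 57 fell with age at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1393 genes, where chance gives 453.8 on average, with a wider spread if genes are not independent. Of 100 splits of the arrays, the real one included, 2 gave as many. Most changes were small: the median size of the called changes was 0.30 log2 units, 10 genes rose over 2-fold and 1 fell over 2-fold. The log2 difference, aged minus young, was 3.0 ± 0.39 (SE) for Cd74 (limma, Benjamini-Hochberg adjusted p = 5.36e-05) and 2.94 ± 0.34 for C3 (limma, Benjamini-Hochberg adjusted p = 1.36e-05). For both genes 13 of the 14 aged arrays lay above every young array. The exception was aged impaired replicate 1, at 4.79 for Cd74 and 4.88 for C3. Young signals of both genes lay close to the limit of 4 set for dim probe sets, so the folds rest on the background correction the values carried. The young means of Fcgr2b (3.79), Anxa4 (3.61) and RT1-CE12 (3.50), named below, lay under that limit, so the sizes of their rises against young arrays are uncertain too. Mgst1 rose by 1.46 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 1.41e-07), with all 14 aged arrays above the young ones. Nat8f3, of a family of N-acetyltransferases, rose by 2.31 ± 0.28, the ceramidase Acer2 by 2.21 ± 0.24 and the C1 inhibitor Serping1 by 1.80 ± 0.36. The other genes with the largest rises were the connective tissue growth factor Ccn2 at 1.78 ± 0.29, Gpnmb, a glycoprotein of phagocytic cells, at 1.45 ± 0.20, the inhibitory IgG receptor Fcgr2b at 1.24 ± 0.19, the annexin Anxa4 at 1.01 ± 0.17, the lysosomal protease Ctsz at 0.99 ± 0.13 and the scavenger receptor Colec12 at 0.98 ± 0.23. Their adjusted p ranged from 8.02e-06 for Acer2 to 0.0135 for Colec12 (limma, Benjamini-Hochberg).

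**Figure D1:**
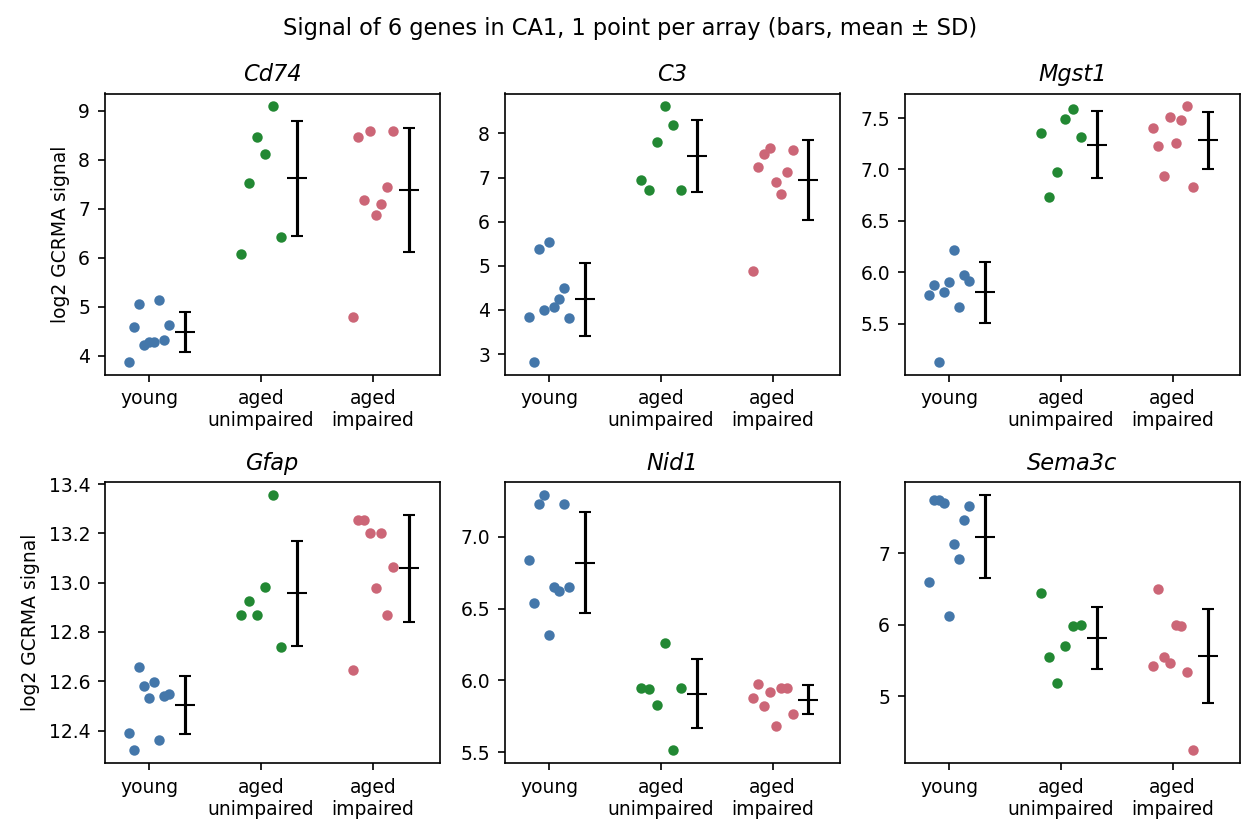
Signal of Cd74, C3, Mgst1, Gfap, Nid1 and Sema3c in log2 units (vertical axes) in the 9 young, 6 aged unimpaired and 8 aged impaired arrays, with 1 point per array and bars for the mean ± SD of each group. The aged arrays of both groups lie above the young ones for Mgst1 and below them for Nid1, and aged impaired replicate 1 is the lowest aged array for Cd74 and C3.

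Sema3c gave the largest fall, with a log2 difference of -1.56 ± 0.23 (limma, Benjamini-Hochberg adjusted p = 2.16e-04), and 12 of the 14 aged arrays lay below every young array. Nid1 changed by -0.93 ± 0.10 (limma, Benjamini-Hochberg adjusted p = 9.32e-06) and lay below the young range in 14 of 14 aged arrays. The receptor tyrosine phosphatase Ptpro changed by -1.0 ± 0.23, the growth factor Igf2 by -0.84 ± 0.16, the type IV collagen chain Col4a5 by -0.76 ± 0.15, the small proteoglycan Dcn by -0.71 ± 0.15 and the zinc transporter Tmem163 by -0.68 ± 0.13. Csrp2 at -0.55 ± 0.14, the matrix protein Fbln2 at -0.53 ± 0.15, the endocytic adaptor Dab2 at -0.50 ± 0.14, Xk at -0.48 ± 0.12 and Fstl5 at -0.46 ± 0.10 completed the 12 largest falls, with adjusted p from 9.32e-06 for Nid1 to 0.0448 for Fbln2 (limma, Benjamini-Hochberg). Some of these calls depended on which arrays were in the fit. Of the 23 fits that left 1 array out, 12 lost Fbln2, 10 lost Dab2, 4 lost Xk and 3 (without young replicate 3, 4 or 9) lost Csrp2. Their adjusted p reached 0.0974, 0.0778, 0.0665 and 0.0528 (limma, Benjamini-Hochberg). The signal of Xk in aged arrays lay near the limit of 4 for dim probe sets, so the size of its fall is uncertain. It ran from 3.80 to 4.77 in impaired and from 3.80 to 4.48 in unimpaired arrays.

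Among genes fixed in advance, the astrocyte filament gene Gfap rose by 0.51 ± 0.07 and the complement subunit C1qa by 0.55 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 2.05e-04 and 2.93e-04). Other panel genes did not pass. Their log2 differences were 0.02 ± 0.03 for the myelin gene Mbp, -0.19 ± 0.43 for the choroid plexus gene Ttr, -0.12 ± 0.11 for Npy, 0.02 ± 0.12 for Sst, 0.02 ± 0.05 for Gad1, -0.16 ± 0.20 for Gad2 and 0.01 ± 0.11 for Reln. They were -0.29 ± 0.18 for Bdnf, 0.30 ± 0.21 for Arc, 0.05 ± 0.13 for Egr1 and 0.05 ± 0.07 for Calb1. No probe set of C4a or C4b passed the filter with a single symbol.

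Among gene lists fixed before the data were examined, those of microglia rose together. Of 21 measured markers of microglia and macrophages, 10 rose and none fell (12 rose adjusted over the list alone), with a median log2 difference of 0.28. The set test camera gave an adjusted p of 5.83e-14, and adjusted p = 0.0146 with an estimated correlation. Fcer1g, a signalling chain of Fc receptors, rose by 0.59 ± 0.08, and the lysosomal protease Ctss by 0.32 ± 0.05. Of 16 phagocytic and disease-associated microglia genes, 10 rose (12 rose and 1 fell adjusted over the list alone; median 0.21; camera adjusted p = 5.23e-12, and adjusted p = 0.0146 with an estimated correlation). Ctsd rose by 0.42 ± 0.06 and Cd63 by 0.35 ± 0.06. Of 6 complement genes, 5 rose (5 adjusted over the list alone; median 0.68; camera adjusted p = 2.82e-09, and adjusted p = 0.0360 with an estimated correlation). The complement protease C1s rose by 0.80 ± 0.18. Of 10 reactive astrocyte genes, 4 rose (7 adjusted over the list alone; median 0.33; camera adjusted p = 7.32e-08, and adjusted p = 0.0360 with an estimated correlation). Beside C3 and Gfap these were the intermediate filament Vim, by 0.49 ± 0.09, and the small heat shock protein Cryab, by 0.41 ± 0.09. These lists overlap, since 9 of the 16 phagocytic genes, 4 of the 6 complement genes and 4 of the 10 reactive astrocyte genes also stand in another list. Of the 42 lists tested, 17 passed camera, and the 4 just named were the only ones that held with an estimated correlation.

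Genes of lysosomes, antioxidant defence and glia rose in part, in lists whose calls were lost with an estimated correlation. In the lysosome and autophagy list 11 of 38 genes rose (13 adjusted over the list alone; camera adjusted p = 7.32e-08, but adjusted p = 0.0874 with an estimated correlation). The cholesterol-binding protein Npc2, at 0.54 ± 0.06, and Lamp2, at 0.32 ± 0.04, led them. In the antioxidant and glutathione list 7 of 28 rose (11 adjusted over the list alone; camera adjusted p = 1.43e-07, but adjusted p = 0.0874 with an estimated correlation). The glutathione transferases Gstp1, at 0.43 ± 0.04, and Gsta1, at 0.54 ± 0.07, led this list, with the regulator Nfe2l2 at 0.31 ± 0.06. Of 27 astrocyte markers 6 rose (9 adjusted over the list alone; camera adjusted p = 8.92e-06, but adjusted p = 0.296 with an estimated correlation). Agt rose by 0.25 ± 0.05 and S100b by 0.14 ± 0.03. Of 26 oligodendrocyte and myelin genes 6 rose and 1 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0171, but adjusted p = 0.620 with an estimated correlation). Qdpr, which recycles biopterin, rose by 0.42 ± 0.06 and Bcas1 by 0.36 ± 0.06.

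Stress hormone and antigen presentation lists showed fewer calls. Of 19 glucocorticoid-responsive genes 4 rose (5 adjusted over the list alone; camera adjusted p = 0.00152, but adjusted p = 0.296 with an estimated correlation). The kinase Sgk1 rose by 0.81 ± 0.17 and the transcription factor Klf15 by 0.42 ± 0.07. Of 11 MHC class I and antigen processing genes 2 rose (3 adjusted over the list alone; camera adjusted p = 0.0162, but adjusted p = 0.140 with an estimated correlation). They were B2m, the light chain of class I molecules, at 0.31 ± 0.05, and RT1-CE12 at 0.54 ± 0.12. Of 9 interferon response genes 2 rose (4 adjusted over the list alone; camera adjusted p = 0.00544, but adjusted p = 0.140 with an estimated correlation). Ifitm3 rose by 0.45 ± 0.12 and Psme1 by 0.22 ± 0.06, by calls lost in 12 and 2 of the 23 leave-outs. In the MHC class II list Cd74 and Ctss rose among 6 genes (2 rose and 1 fell adjusted over the list alone), and the list did not pass (median 0.06, mean 0.54, camera adjusted p = 0.0765).

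**Figure D2:**
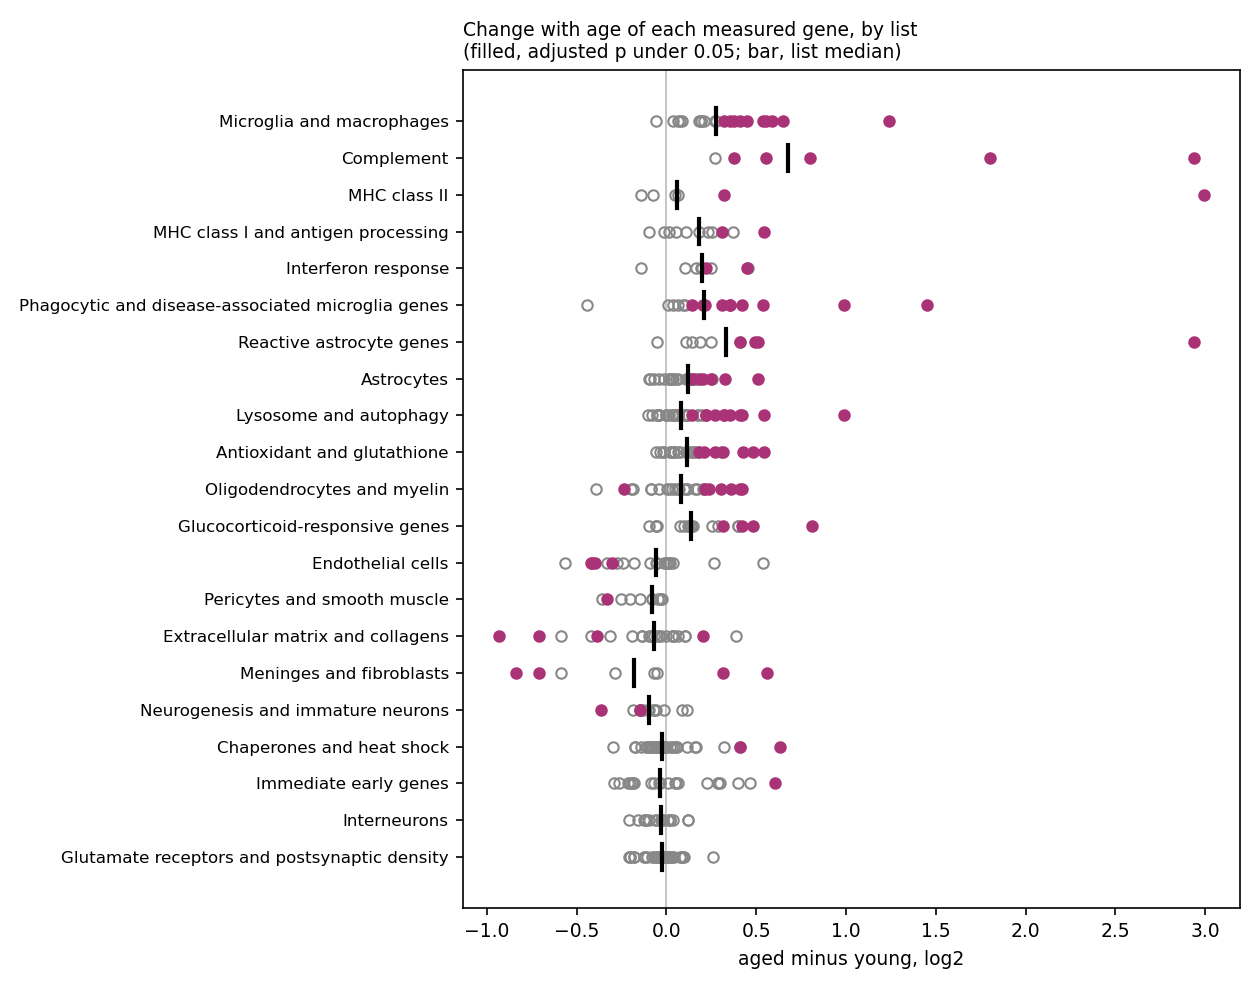
Log2 difference, aged minus young, of each measured gene (horizontal axis) in 21 gene lists fixed before the data were examined, with filled points for genes at an adjusted p under 0.05 (limma, Benjamini-Hochberg), open points for the others and a bar at each list's median. All called genes of the microglia, complement and reactive astrocyte lists lie above 0, and no gene of the interneuron or glutamate receptor lists is filled.

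Some vessel and matrix genes fell, in lists whose calls were lost with an estimated correlation. Of 21 endothelial markers 4 fell (1 rose and 5 fell adjusted over the list alone; camera adjusted p = 3.65e-04, but adjusted p = 0.275 with an estimated correlation). The transporter Slco1c1 changed by -0.41 ± 0.08 and the endothelial transcription factor Sox17 by -0.40 ± 0.09, while the calls of Sox18 at -0.42 ± 0.12 and Ramp2 at -0.30 ± 0.09 were lost in 18 and 16 of the 23 leave-outs. Of 11 pericyte and smooth muscle genes only Myh11 fell, by 0.33 ± 0.09 (3 fell adjusted over the list alone; camera adjusted p = 4.96e-04, but adjusted p = 0.138 with an estimated correlation), a call lost in 10 leave-outs. Of 25 matrix and collagen genes 3 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00152, but adjusted p = 0.0874 with an estimated correlation). Nid1, Dcn and the collagen Col4a1, at -0.39 ± 0.09, fell and the protease inhibitor Timp2 rose by 0.20 ± 0.05. Averaging the probe sets of a gene ended the calls of Col4a1 and Timp2. Markers of meninges and fibroblasts went both ways, with 2 up and 2 down among 8 measured (2 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.112). Igf2 and Dcn fell, while Ptgds rose by 0.56 ± 0.10 and Aebp1 by 0.32 ± 0.08, the last by a call lost in 4 leave-outs. Of 14 neurogenesis and immature neuron genes 2 fell (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.00191, but adjusted p = 0.261 with an estimated correlation). Sox4 changed by -0.36 ± 0.07 and Stmn2 by -0.15 ± 0.04, the latter by a call lost in 14 leave-outs.

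Neuronal lists changed little. None of 18 interneuron markers, 36 glutamate receptor and postsynaptic genes, 38 presynaptic genes, 15 GABA genes, 34 calcium signalling genes, 16 markers of CA3 and CA2, or 16 markers of dentate granule cells passed, also adjusted over the list alone. Of 23 immediate early genes the growth arrest gene Gadd45b rose, by 0.61 ± 0.12 (1 adjusted over the list alone; camera adjusted p = 0.553). Of 36 chaperone genes Hspb8, at 0.63 ± 0.11, and Cryab rose (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0821). The medians of the chaperone and immediate early lists, both -0.03, differed in sign from their means of 0.02 and 0.04. No gene passed among 30 of the proteasome, 50 of oxidative phosphorylation, 13 of NF-kB and cytokine signalling, 22 of histone and DNA modification, 11 of the cell cycle or 6 of choroid plexus and ependyma, also adjusted over the list alone. None passed among 12 markers of oligodendrocyte precursors (3 fell adjusted over the list alone; median -0.09; camera adjusted p = 0.00790, but adjusted p = 0.348 with an estimated correlation) or 17 neurotrophin and growth factor genes (1 rose adjusted over the list alone). Of 28 cytosolic ribosomal protein genes Rps6 rose (3 adjusted over the list alone; median 0.08; camera adjusted p = 1.02e-06, but adjusted p = 0.390 with an estimated correlation). Elsewhere single genes passed: Ldhb of 23 glycolysis genes (2 adjusted over the list alone), Kcna1 of 33 potassium and sodium channel genes (5 adjusted over the list alone), Fdft1 and Insig1 of 19 cholesterol genes (3 rose and 1 fell adjusted over the list alone), and Bhlhe41 and Nr1d2 of 16 clock genes (3 adjusted over the list alone). Igfbp6 rose and Igf2 fell of 19 insulin and IGF genes, Ccn2 rose of 18 thalamic and cortical neighbour markers (2 adjusted over the list alone), and Dcn fell of 8 markers of CA1 pyramidal cells. Of the 23 leave-outs, 17 lost the call of Igfbp6, 16 that of Kcna1, 15 that of Nr1d2, 8 that of Fdft1 and 7 that of Insig1. Ldhb, Rps6, Kcna1, Fdft1, Insig1, Bhlhe41, Nr1d2 and Igfbp6 were named after their values were seen. Only 4 blood cell genes were measured, too few for a set test, and the globin Hbb differed by -0.05 ± 0.15 (limma, Benjamini-Hochberg adjusted p = 0.922).

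The split of the calls into higher and lower depended on scaling: with each array centred on its median over the tested genes, 241 rose and 136 fell, so that 63.9% of the calls rose in place of 83.1%. Leaving out young replicate 2 lowered the count to 224 genes.

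Aged rats with impaired learning were next compared with young rats. Their arrays are 8 of the 14 that entered the aged mean above. Cd74 was 7.42-fold, C3 6.51-fold and the phagocyte glycoprotein Gpnmb 3.02-fold higher in impaired than in young CA1, and Mgst1 was 2.78-fold higher. The ubiquitin ligase gene Rnf6 was 3.65-fold lower and Sema3c 3.18-fold lower. Limma with Benjamini-Hochberg adjustment gave 280 genes that rose and 65 that fell. At an unadjusted p under 0.05 there were 1502 genes, where chance gives 453.8 on average, with a wider spread if genes are not independent. Of 100 splits of the impaired and young arrays, the real one included, 2 gave as many. In log2 units Cd74 rose by 2.89 ± 0.45, C3 by 2.70 ± 0.39, Nat8f3 by 2.31 ± 0.32, Acer2 by 2.16 ± 0.27 and Serping1 by 1.94 ± 0.41. Ccn2 rose by 1.78 ± 0.33, Gpnmb by 1.59 ± 0.23, Mgst1 by 1.47 ± 0.14, Fcgr2b by 1.32 ± 0.21, Anxa4 by 1.13 ± 0.20, Ctsz by 1.04 ± 0.15 and Aadat, an aminotransferase of kynurenine metabolism, by 1.0 ± 0.11. Adjusted p for these 12 ranged from 7.10e-07 for Mgst1 to 0.00805 for Serping1 (limma, Benjamini-Hochberg). Rnf6 changed by -1.87 ± 0.43 (limma, Benjamini-Hochberg adjusted p = 0.0143) with a wide spread, at 6.12 ± 1.43 (SD, n = 8) in impaired against 7.99 ± 0.46 (SD, n = 9) in young arrays, and aged impaired replicate 1 was lowest at 3.12. Sema3c changed by -1.67 ± 0.26, Ptpro by -0.96 ± 0.26, Nid1 by -0.95 ± 0.12, Col4a5 by -0.75 ± 0.18 and Igf2 by -0.72 ± 0.18. Fbln2 changed by -0.65 ± 0.17, L3mbtl3 by -0.62 ± 0.15, Tmem163 by -0.61 ± 0.15 and the chromodomain gene Cdyl2 by -0.49 ± 0.11. The kinesin Kif26b changed by -0.62 ± 0.08, although 1 of its 3 measured probe sets went the other way and averaging them ended the call. Hcrt, the orexin precursor made in the hypothalamus, was lower in impaired than in young arrays, at 3.11 ± 0.40 (SD, n = 8) against 4.25 ± 0.77 (SD, n = 9). The impaired mean lay under the limit of 4 for dim probe sets, so the size of this fall is not known. Between aged and young arrays Rnf6, Hcrt, L3mbtl3 and Cdyl2 did not pass (limma, Benjamini-Hochberg adjusted p = 0.0574, 0.0576, 0.105 and 0.212). Leaving out single arrays ended the calls of Ptpro in 12 fits, of Fbln2 and Hcrt in 6 each, and of Tmem163 without aged impaired replicate 5 or 6.

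Of 42 lists, 18 passed camera between impaired and young CA1, and 2 of them, both of microglia, held with an estimated correlation, while the complement list did not. Of 21 microglia markers 10 rose (17 adjusted over the list alone; median 0.32; camera adjusted p = 4.07e-15, and adjusted p = 0.010 with an estimated correlation). Fcer1g rose by 0.68 ± 0.09, Cd53 by 0.74 ± 0.13 and Ctss by 0.34 ± 0.06. Of 16 phagocytic microglia genes 10 rose (12 adjusted over the list alone; median 0.24; camera adjusted p = 8.66e-13, and adjusted p = 0.010 with an estimated correlation), Ctsd by 0.43 ± 0.07. Of the complement genes C3, C1qa, Serping1 and C1s rose (5 adjusted over the list alone; camera adjusted p = 3.38e-07, but adjusted p = 0.0707 with an estimated correlation), C1qa by 0.50 ± 0.10. Of 10 reactive astrocyte genes 4 rose (7 adjusted over the list alone; camera adjusted p = 5.16e-07, but adjusted p = 0.0707 with an estimated correlation). Gfap rose by 0.56 ± 0.09, Vim by 0.53 ± 0.10 and Ggta1, which makes the alpha-galactose epitope, by 0.31 ± 0.06. In the lysosome list 10 of 38 genes rose (12 adjusted over the list alone; camera adjusted p = 2.14e-07, but adjusted p = 0.112 with an estimated correlation), with Npc2 at 0.59 ± 0.07. Antioxidant genes rose in 6 of 28 cases (13 adjusted over the list alone; camera adjusted p = 2.71e-08, but adjusted p = 0.0707 with an estimated correlation), with Gstp1 at 0.52 ± 0.05. Of 26 oligodendrocyte genes 6 rose (10 rose and 2 fell adjusted over the list alone; camera adjusted p = 3.66e-04, but adjusted p = 0.452 with an estimated correlation), Qdpr at 0.47 ± 0.07 and the lipocalin Apod at 0.40 ± 0.08.

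Of 36 chaperones 1 rose and 2 fell in impaired rats (2 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.00265, but adjusted p = 0.505 with an estimated correlation). Hspb8 rose by 0.67 ± 0.13. The endoplasmic reticulum chaperones Pdia4, at -0.37 ± 0.10, and Hspa5, at -0.24 ± 0.07, fell by calls lost in 17 and 18 of the 23 leave-outs. Of 23 immediate early genes 1 rose and 2 fell (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0541). Gadd45b rose by 0.57 ± 0.14, and Dusp6, at -0.44 ± 0.12, and Homer1, at -0.27 ± 0.07, fell by calls lost in 7 and 9 leave-outs. Of 21 endothelial markers only Slco1c1 fell, by 0.45 ± 0.09 (1 adjusted over the list alone; camera adjusted p = 0.0584). In the panel, C3, Cd74, C1qa and Gfap passed, and Mbp differed by 0.03 ± 0.04, Ttr by 0.08 ± 0.49, Npy by -0.13 ± 0.12, Sst by 0.04 ± 0.14, Gad1 by 0.09 ± 0.06 and Gad2 by -0.16 ± 0.23. Reln differed by 0.14 ± 0.12, Bdnf by -0.29 ± 0.20, Arc by 0.08 ± 0.23, Egr1 by -0.06 ± 0.14 and Calb1 by -0.04 ± 0.08 without passing. Centring each array gave 293 genes up and 149 down, with 66.3% rising in place of 81.2%, and leaving out aged impaired replicate 6 lowered the count to 228.

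Aged rats with preserved learning differed from young rats in fewer called genes, led by the same immune transcripts. C3 was 9.52-fold and Cd74 8.78-fold higher in unimpaired than in young CA1, and Nat8f3 was 4.98-fold and Acer2 4.86-fold higher. Sema3c was 2.68-fold and Igf2 2.00-fold lower. Limma with Benjamini-Hochberg adjustment gave 56 genes that rose and 13 that fell. At an unadjusted p under 0.05 there were 893 genes, where chance gives 453.8 on average, with a wider spread if genes are not independent. Of 100 splits of the unimpaired and young arrays, the real one included, 4 gave as many. The rises in log2 units were 3.25 ± 0.42 for C3, 3.13 ± 0.48 for Cd74, 2.32 ± 0.35 for Nat8f3, 2.28 ± 0.30 for Acer2, 1.78 ± 0.36 for Ccn2 and 1.43 ± 0.15 for Mgst1. They were 1.26 ± 0.25 for Gpnmb, 1.14 ± 0.23 for Fcgr2b, 0.97 ± 0.14 for the potassium channel Kcnj16, 0.94 ± 0.12 for Aadat, 0.93 ± 0.16 for the lectin receptor Cd302 and 0.92 ± 0.16 for Ctsz, with adjusted p from 1.16e-05 for Mgst1 to 0.0136 for Fcgr2b (limma, Benjamini-Hochberg). The falls were -1.42 ± 0.28 for Sema3c, -1.0 ± 0.19 for Igf2, -0.91 ± 0.13 for Nid1, -0.88 ± 0.19 for Dcn, -0.78 ± 0.17 for Tmem163 and -0.60 ± 0.13 for Fstl5. Smaller falls were -0.58 ± 0.11 for Sox17, -0.48 ± 0.11 for Nrep, -0.43 ± 0.10 for the zinc finger gene Zfp658, -0.40 ± 0.08 for Ndn, -0.28 ± 0.06 for Arhgdig and -0.25 ± 0.06 for the zinc transporter Slc39a10. Of these, Slc39a10 and Zfp658 lost their calls in 10 of the 23 leave-outs, Nrep and Arhgdig in 8 and Fstl5 in 4. Tmem163 lost its call without aged unimpaired replicate 4 or 5, Dcn without 2 or 4, Ndn without 4 or 7, and Gpnmb without 4.

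Between unimpaired and young rats 19 of 42 lists passed camera, and 0 held with an estimated correlation. Of 6 complement genes C3, C1qa at 0.62 ± 0.10 and C1qc at 0.50 ± 0.11 rose (5 adjusted over the list alone; camera adjusted p = 7.44e-10, but adjusted p = 0.0554 with an estimated correlation). Of 21 microglia markers 5 rose (11 adjusted over the list alone; median 0.29; camera adjusted p = 4.83e-08, but adjusted p = 0.0554 with an estimated correlation). Of 16 phagocytic genes 4 rose (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 9.83e-08, but adjusted p = 0.0554 with an estimated correlation), with Ctsd at 0.41 ± 0.08. Of 10 reactive astrocyte genes C3, Gfap at 0.45 ± 0.09 and Cryab at 0.56 ± 0.11 rose (4 adjusted over the list alone; camera adjusted p = 1.20e-06, but adjusted p = 0.0554 with an estimated correlation). In the lysosome list 6 of 38 rose (11 adjusted over the list alone; camera adjusted p = 2.44e-06, but adjusted p = 0.140 with an estimated correlation). Gsta1, at 0.51 ± 0.08, and Gstp1, at 0.30 ± 0.05, rose of 28 antioxidant genes (4 adjusted over the list alone; camera adjusted p = 3.97e-04, but adjusted p = 0.214 with an estimated correlation). Of 21 endothelial markers Sox17 fell (5 adjusted over the list alone; median -0.11; camera adjusted p = 1.16e-07, but adjusted p = 0.0860 with an estimated correlation). None of 11 pericyte genes passed (2 fell adjusted over the list alone; median -0.20; camera adjusted p = 2.44e-06, but adjusted p = 0.0554 with an estimated correlation). Igf2 and Dcn fell among 8 meningeal markers (2 rose and 4 fell adjusted over the list alone; median -0.27; camera adjusted p = 0.00508, but adjusted p = 0.140 with an estimated correlation). Of 26 oligodendrocyte genes Bcas1 at 0.39 ± 0.07, Qdpr at 0.36 ± 0.07 and Cryab rose (4 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.882). No glucocorticoid-responsive gene of 19 passed (5 rose adjusted over the list alone; camera adjusted p = 3.44e-05, but adjusted p = 0.163 with an estimated correlation), with Sgk1 at 0.81 ± 0.21. The calls of Cryab (without aged unimpaired replicate 4), C1qc (without 3 or 4) and Qdpr (without 4 or 5) were lost in leave-outs.

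In the panel, Mbp differed by -0.01 ± 0.04, Ttr by -0.55 ± 0.53, Npy by -0.10 ± 0.13, Gad1 by -0.07 ± 0.06 and Gad2 by -0.16 ± 0.25. Reln differed by -0.16 ± 0.13, Bdnf by -0.29 ± 0.22, Arc by 0.58 ± 0.25, Egr1 by 0.18 ± 0.16 and Calb1 by 0.16 ± 0.08 without passing, and the 2 groups' means of Sst were 9.07 in both. Centring each array gave 50 genes up and 30 down, with 62.5% rising in place of 81.2%. The count fell to 35 without aged unimpaired replicate 4 and rose to 149 with limma's array quality weights.

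The changes of impaired and of unimpaired rats against young were compared, both being measured against the same young arrays. Of the 56 genes that rose in unimpaired rats, 52 also rose in impaired rats, and of the 13 that fell, 6 also fell. Regardless of the threshold, all 56 and all 13 had the same sign in impaired rats. Of the genes called in impaired rats, 277 of 280 that rose and 62 of 65 that fell had the same sign in unimpaired rats. The shared young arrays favour this. With the young arrays split into 4 and 5, so that the comparisons shared none, an average of 20.2 genes rose in both, where independent lists would share 0.384, and 1.32 fell in both, where they would share 0.0202. Across genes, which are not independent replicates, the changes against young correlated at 0.706. Groups simulated without any change against the same young arrays gave 0.435 on average, since the young arrays are shared. The covariance was 0.0159 against a simulated 0.00403. With the young arrays split, the correlation averaged 0.452 and the covariance 0.0119 over 126 splits. Both changes had the same sign in 69.3% of genes, against 64.3% in the simulations and 57.2% with the young arrays split. The simulated values are a reference only for the comparisons that share all young arrays. With the young arrays split, unchanged groups would have no such built-in agreement, and the smaller young sets add noise.

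The last comparison asked what set impaired apart from unimpaired aged rats. No gene passed in limma with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.256. At an unadjusted p under 0.05 there were 629 genes, where chance gives 453.8 on average, with a wider spread if genes are not independent. Of 100 splits of the aged arrays, the real one included, 16 gave as many. Array quality weights or trended robust moderation in limma also gave 0 genes. The genes with the smallest p that lay higher in impaired rats were Lgi3 by 0.29 ± 0.07, Gstp1 by 0.23 ± 0.05, the cold-induced RNA-binding protein Rbm3 by 0.44 ± 0.11, Ggta1 by 0.28 ± 0.07 and Tmem106c by 0.39 ± 0.10. Those that lay lower were Ctxnd1 by a difference of -0.60 ± 0.13, Rfxap, part of a regulator of MHC class II genes, by -0.37 ± 0.08, Kif26b by -0.41 ± 0.09, the receptor Gpr161 by -0.32 ± 0.07 and Cdyl2 by -0.55 ± 0.13. Their adjusted p ran from 0.256 to 0.562 (limma, Benjamini-Hochberg), and 1 of 3 probe sets of Kif26b went the other way. The genes of the large age changes did not pass between the aged groups: impaired minus unimpaired, Cd74 differed by -0.24 ± 0.50, C3 by -0.55 ± 0.43, C1qa by -0.12 ± 0.11 and Gfap by 0.10 ± 0.09. The first 2 values leaned on aged impaired replicate 1, without which Cd74 differed by 0.13 and C3 by -0.25. Cd74 also changed sign without aged unimpaired replicate 5, to 0.05. In the rest of the panel Mbp differed by 0.04 ± 0.04, Ttr by 0.63 ± 0.54, Npy by -0.03 ± 0.13, Sst by 0.04 ± 0.15, Gad1 by 0.16 ± 0.06 and Reln by 0.30 ± 0.13. Arc differed by -0.50 ± 0.26, Egr1 by -0.24 ± 0.16 and Calb1 by -0.21 ± 0.09, and the standard errors of Gad2 and Bdnf, at 0.25 and 0.22, exceeded their differences. A fit to the aged arrays alone called 1 gene, the activin subunit Inhba, at -0.65 ± 0.09 (limma, Benjamini-Hochberg adjusted p = 0.0419), which in the fit of all 3 groups had a standard error of 0.32 and an adjusted p of 0.725. Inhba was named after its value was seen.

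Small shifts of whole lists passed camera between the aged groups, and none held with an estimated correlation or in fry. Chaperones lay lower in impaired rats (median -0.07; camera adjusted p = 3.56e-05, but adjusted p = 0.486 with an estimated correlation), as did immediate early genes (median -0.16; camera adjusted p = 8.02e-05, but adjusted p = 0.486 with an estimated correlation) and markers of CA1 pyramidal cells (median -0.17; camera adjusted p = 0.0176, but adjusted p = 0.486 with an estimated correlation). The immediate early list varied widely between single arrays. Its mean, relative to the average array, was 0.43 and 0.48 in aged unimpaired replicates 3 and 5 and -0.46 in aged impaired replicate 7, and lay between -0.19 and 0.21 in the other aged arrays. Adjusted over the list alone, 1 immediate early gene and 1 CA1 marker fell and no chaperone did. The phosphatase Dusp6 differed by -0.56 ± 0.13, Hspa5 by -0.23 ± 0.08 and Dnajb1 by -0.23 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 0.256, 0.562 and 0.619). Markers of other cells and regions lay higher in impaired rats: oligodendrocytes (median 0.09; camera adjusted p = 5.61e-05, but adjusted p = 0.486 with an estimated correlation), microglia (median 0.15; 3.03e-04, but adjusted p = 0.486 with an estimated correlation), endothelial cells (median 0.09; 0.00141, but adjusted p = 0.486 with an estimated correlation). So did meninges (median 0.21; 0.0132, but adjusted p = 0.486 with an estimated correlation), pericytes (median 0.09; 0.0373, but adjusted p = 0.486 with an estimated correlation), dentate granule cells (median 0.14; 0.0219, but adjusted p = 0.486 with an estimated correlation), CA3 and CA2 (median 0.10; 0.0402, but adjusted p = 0.695 with an estimated correlation) and astrocytes (median 0.04; 0.0450, but adjusted p = 0.776 with an estimated correlation). No member of these lists passed, also adjusted over the list alone. The lists of phagocytic microglia genes (median 0.08), antioxidant genes (median 0.04) and glycolysis genes (median 0.04) lay higher too (camera adjusted p = 0.00141, 0.00174 and 0.00524, but adjusted p = 0.486, 0.486 and 0.642 with an estimated correlation), and Gstp1 alone rose adjusted over the list alone. Opalin, a myelin gene, differed by 0.34 ± 0.10 and the microglial receptor Csf1r by 0.25 ± 0.09, both with an adjusted p of 0.562 (limma, Benjamini-Hochberg). Without the 3 arrays of lowest correlation, a choice made after seeing the data, 6 lists passed camera in place of 14.

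An age score, the mean of the 280 rising genes minus the mean of the 57 falling genes in each array, was 0.20 ± 0.12 (SD, n = 9) in young, 0.92 ± 0.11 (SD, n = 6) in aged unimpaired and 1.01 ± 0.08 (SD, n = 8) in aged impaired rats. The impaired mean was higher than the unimpaired mean by 0.0929, which did not pass a 2-sided exact permutation test over all splits of the aged arrays (p = 0.10). Of the 23 leave-outs, 6 passed that test: without aged impaired replicate 1 (0.123, exact p = 0.00350) or 8 (0.111, exact p = 0.0315), aged unimpaired replicate 3 (0.143, exact p = 0.00622) or 5 (0.137, exact p = 0.0132), and young replicate 1 (0.117, exact p = 0.0350) or 4 (0.138, exact p = 0.00799). Centring each array also passed (0.110, exact p = 0.0306). Leaving out a young array changes only the genes in the score, since the aged arrays tested stay the same. The choice of genes alone thus moved the result. In the fit to all arrays, other choices of genes did not pass. The difference was 0.0788 with the 200 genes of smallest p (exact p = 0.184), 0.0597 with the rising genes alone (exact p = 0.214) and 0.0332 with the falling genes alone (exact p = 0.419).

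**Figure D3:**
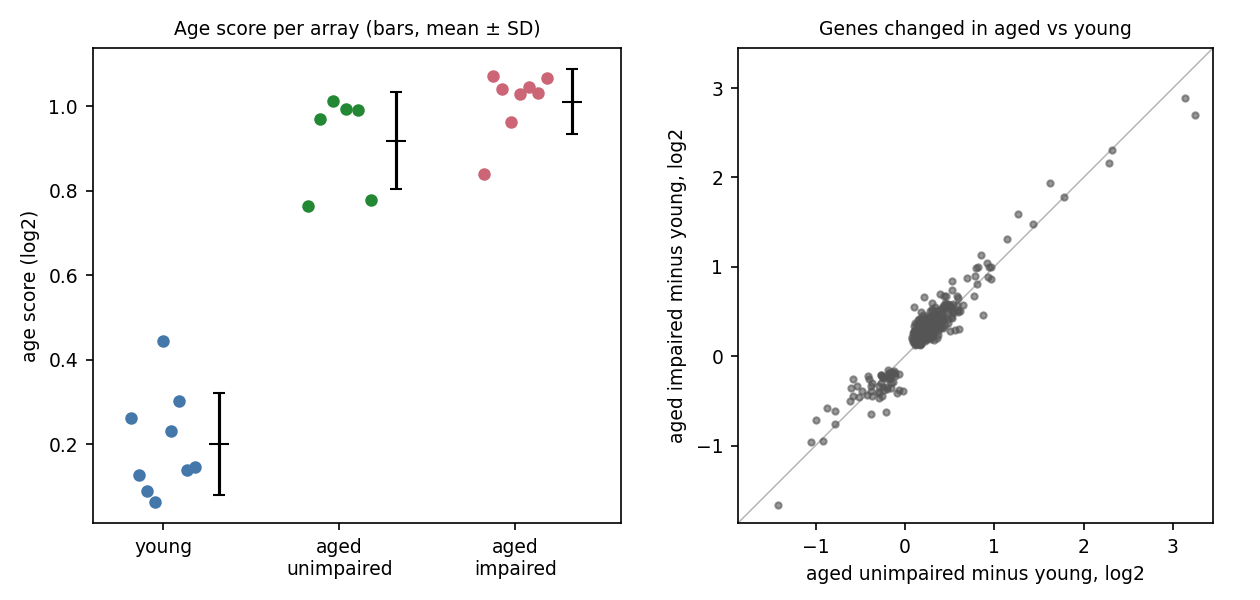
Left, age score per array (log2 units, vertical axis) in the 9 young, 6 aged unimpaired and 8 aged impaired arrays, with 1 point per array and bars for the mean ± SD. Right, log2 difference from young in aged unimpaired (horizontal axis) and aged impaired arrays (vertical axis) of the 337 genes called between aged and young arrays, with a line of equality. These genes were chosen on the mean of both aged groups, which favours the same sign on both axes.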

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

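All tests of explanations in this part were chosen after the results were seen.

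Single arrays lay far from the rest of their group in 34 of the 345 groups of arrays examined, over 115 measures, where chance gives about 1 in 20, or 17.25. The value given for each is the array's gap to its nearest neighbour as a share of its group's range. Aged impaired replicate 1 was lowest for Cd74 (0.549), C3 (0.631) and the age score (0.527). Aged impaired replicate 7 was lowest for Bdnf (0.565) and Egr1 (0.564), replicate 3 for Xk (0.543) and replicate 8 for Fbln2 (0.612). The highest impaired arrays were replicate 5 for Csrp2 (0.646), 6 for Ttr (0.832) and Col4a1 (0.540), 4 for Calb1 (0.595) and 2 for Ptgds (0.544). Among aged unimpaired arrays, replicate 3 was highest for Ccn2 (0.630) and lowest for Apod (0.629) and for the difference between 3 prime and 5 prime control probe sets (0.637). Replicate 5 was highest for Fcgr2b (0.684) and Hspb8 (0.750) and lowest for Myh11 (0.810). Replicate 4 was highest for Aebp1 (0.706) and Insig1 (0.655) and lowest for Igfbp6 (0.663), and replicate 2 was lowest for Xk (0.775) and highest for Gad2 (0.678).

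Among young arrays, replicate 2 was lowest for Aebp1 (0.559) and Cd53 (0.700), replicate 4 was highest for Dab2 (0.507) and lowest for Hspb8 (0.535), and replicate 5 was highest for Npy (0.545) and lowest for L3mbtl3 (0.520). Replicate 7 was highest for Aadat (0.525) and lowest for Gadd45b (0.645). The highest young arrays for Apod (0.619), Tmem163 (0.551) and Nr1d2 (0.582) were replicates 3, 8 and 1.

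The difference between impaired and unimpaired aged rats passed camera at the preset correlation for 14 gene lists, none of which passed with an estimated correlation. Their median log2 differences were -0.0672 for chaperones, -0.161 for immediate early genes and -0.168 for CA1 pyramidal cells. They were 0.0798 for phagocytic microglia genes, 0.149 for microglia, 0.0416 for astrocytes, 0.0872 for oligodendrocytes, 0.0905 for endothelial cells, 0.0871 for pericytes and 0.206 for meninges. For CA3 and CA2 pyramidal cells the value was 0.0973, for dentate granule cells 0.136, for glycolysis 0.0398 and for antioxidant genes 0.0439. Outside the genes analysed, 81 of 3986 probe sets without a single gene symbol also passed between aged and young arrays (limma, Benjamini-Hochberg), 61 of them higher in aged CA1.

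The labels name no aged unimpaired replicate 6, and the column of young replicate 9 lies between those of aged unimpaired replicates 5 and 7. Each array was placed between the young (0) and aged (1) means of the other arrays by an age score on genes called without it. Young replicate 9 stood at 0.0883, against 0.636 for the lowest aged array and 0.502 for the highest other young array, with an SD within groups of at most 0.193. A mislabelled aged array was argued against by this value. Why the number is missing stays open.

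Chance splits of the same arrays were set against each count of called genes. Of 100 splits including the real one, 1 called as many genes for aged against young (337, highest other 12). The same held for impaired against young (345, highest other 111) and for unimpaired against young (69, highest other 1). With 100 splits this makes chance unlikely for these counts but does not exclude it. At an unadjusted p under 0.05, 2, 2 and 4 of 100 splits, the real one included, gave as many genes (highest others 1483, 2233 and 1095). For impaired against unimpaired the real count was 0 (highest other 1), which all 100 splits reach whatever the values, so this count says nothing about chance. The 629 genes at an unadjusted p under 0.05 were reached in 16 of 100 splits (highest other 1132), so chance is not excluded for them.

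The rise of microglia, complement and lysosome genes in aged CA1 was weighed against technical explanations. A lower share of neurons would raise markers of other cells alike, but the microglia list mean exceeded the endothelial one by 0.450 ± 0.0535 (0.333 against -0.117). The endothelial list itself fell with age, and the astrocyte and oligodendrocyte lists rose in part. This gap therefore does not settle whether the share of neurons was lower. A difference in RNA quality, as far as the 3 prime to 5 prime difference measures it, was argued against by a fit with that difference. It kept 92.3% of the calls (24 of 26) while 86 other calls were lost. The 26 genes were picked as called and rising. Their median rise of 0.415, against a median size of 0.298 for all calls, favours keeping them, so the comparison with the other calls is uneven. The measure itself did not separate the groups, so the fit could remove little. More blood was argued against by Hbb, at -0.0511 ± 0.151, whose upper bound of 0.261 lay below the median rise of 0.415. The rise was uneven over the microglia list. Fcgr2b rose by 1.24 and Fcer1g by 0.59, but Cx3cr1 (0.21), Csf1r (0.19), P2ry12 (0.18) and Tmem119 (-0.06) were not called. More or more active microglia with age may explain the pattern, and these values cannot part cell number from expression per cell.

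More genes were called against young in impaired than in unimpaired rats. The larger group was argued against as the whole cause. Against young, 28 subsets of 6 impaired arrays called 138 to 487 genes, where the unimpaired arrays called 69. The median of the subsets was 243.5, against 345 with all impaired arrays, so group size may account for part of the gap. The 69 came from the main fit, which held all impaired arrays, so the subsets and the 69 are not fully matched. A wider spread between unimpaired arrays was argued against by their median SD of 0.103, which lay below the 0.145 of impaired and the 0.134 of young arrays. The main fit used 1 spread for all groups, however, so the wider impaired arrays also entered the error of the unimpaired comparison. Array quality weights called 305 genes in impaired and 149 in unimpaired rats, and fits to only the groups compared 239 and 77. The size of the gap thus depended on how the spread was modelled. Larger changes with age in impaired rats cannot be told apart from equal changes: the age score differed by 0.0929 with a standard error of 0.0541 (2-sided exact p = 0.10). Of the 23 leave-outs, 6 passed that test, so the call depended on single arrays and on the genes in the score. Calls in 1 group and not in the other do not show a difference between them.

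The fall of 7 called matrix and vessel genes outside the meninges list was weighed against less meninges in the aged dissections. With the mean of the 8 measured meninges markers in the fit, their median log2 change went from -0.40 to -0.35, and the median standard error from 0.0894 to 0.0990. The fall shrank by 10.8% (jackknife SE 17.1) and 2 of the 7 genes were still called. Of the 8 markers 2 were called up and 2 down. With only the 4 markers that did not pass, picked for that, the fall of the 7 genes shrank by 11.8% (jackknife SE 18.5). Over the wider set of falling genes it shrank by 6.28% (jackknife SE 21.1; 55 genes outside the list, 8 markers) or 0.44% (jackknife SE 15.0; 57 genes, 4 markers), with 19 and 28 genes still called. At these spreads less meninges cannot be told apart from other causes. Fewer endothelial cells cannot be told apart from lower expression per cell, since the mean of all endothelial markers changed by -0.117 ± 0.055 against a median of -0.404 for the 4 called, members chosen for falling. Markers that were not called were mixed. Pecam1 differed by -0.005 and Flt1 by 0.004, while Kdr differed by -0.33, Tek by -0.28 and Abcg2 by 0.54. Age itself stays open and untested as the biological explanation.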

How the results depend on the processing

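The fit without the 3 arrays of lowest correlation (aged impaired replicates 7 and 8, young replicate 5) was chosen after the results were seen. Total counts of called genes stayed within 1.5 times their reported value for every alternative not named here, and the cause was not tested where they did not. Fewer gene lists passed camera with an estimated correlation (4 for aged, 2 for impaired and 0 for unimpaired against young, and 0 for impaired against unimpaired) and fewer passed fry (11, 11 and 0 in the last 3). Array quality weights gave 149 genes for unimpaired against young. Centring the arrays gave an age score difference of 0.110. An adjusted p under 0.10 in limma with Benjamini-Hochberg adjustment gave 524, 531 and 135 genes against young, more by construction. Counts of genes that fell (57 for aged, 65 for impaired and 13 for unimpaired against young) moved more than the totals. They were 105, 134 and 22 after quantile normalization again, 136, 149 and 30 with centred arrays, 22, 18 and 3 with a replicate block, and 121, 135 and 25 at an adjusted p under 0.10. The 13 became 38 with array weights, 22 with the 3 prime to 5 prime covariate and 29 without the 3 arrays, and the 65 became 36 with only the groups compared. With only the aged groups in the fit 1 gene was called between them, and 6 lists passed camera there without the 3 arrays.

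Some groups share replicate numbers. A replicate block in limma gave 159, 165 and 31 genes against young and 1 gene, Dusp6, between the aged groups (-0.54 ± 0.08, Benjamini-Hochberg adjusted p = 0.0427). The numbers did not pair the arrays, since only 1 of 20 same-number pairs correlated over 0.1 (median -0.0519) and 1 of 22 arrays correlated best with its own number.

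Leaving out 1 array gave 224 genes (without young replicate 2) to 407 (without aged impaired replicate 8) for aged, 228 (without aged impaired replicate 6) to 439 (without replicate 8) for impaired and 35 (without aged unimpaired replicate 4) to 86 (without young replicate 5) for unimpaired against young. Genes that fell ran from 39 to 81 (without young replicates 3 and 5), 40 to 90 (without young replicates 8 and 5) and 4 to 26 (without aged unimpaired replicate 4 and young replicate 5). The age score difference ran from 0.0701 (without young replicate 8) to 0.143 (without aged unimpaired replicate 3). No result changed direction while called. Of the values of named genes, 139 lost and 54 gained a call under the other alternatives, and 381 and 55 under leave-outs. The array left out by the submitters could not be added, since its column was blank, and a pseudocount was not tried, since values were already log2. Signals near the limit of 4 limit folds such as that of Cd74.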

Other observations

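All observations in this part were chosen after the values were seen. Of the MHC class II genes, RT1-Db1 was tested and differed by -0.14 ± 0.06 between aged and young arrays (limma, Benjamini-Hochberg adjusted p = 0.230). RT1-Da and RT1-Ba lay too low for the tests. RT1-Da exceeded a log2 signal of 4 in 2 of 8 aged impaired arrays (highest 6.64), 2 of 6 aged unimpaired arrays (highest 6.34) and 0 of 9 young arrays (highest 3.04). RT1-Ba exceeded it in 1 of 8, 1 of 6 and 0 of 9 arrays.

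Fos was high in single arrays of every group, at 5.89 in aged impaired replicate 2, 7.25 and 7.21 in aged unimpaired replicates 3 and 5, and 6.18 in young replicate 8. Dusp1 in the same arrays was 7.14, 8.26, 7.55 and 7.18. Ttr was 9.50 in aged impaired replicate 6 and in young replicate 2. The first 3 principal components held 15.5%, 12.4% and 8.1% of the variance between arrays.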
